A study of Homo sapiens with 12 samples.

How the data were processed

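The series holds 12 expression arrays of HK-2 cells, an immortalised line of human renal proximal tubular epithelium. Per the labels, cells were seeded in 6-well plates 24 h before treatment and treated near 90% confluence with the compound called Di or with its vehicle, and RNA was collected at 12 h or 48 h. The 4 groups are Di at 12 h, control at 12 h, Di at 48 h and control at 48 h, each with 3 biological replicates. Neither the identity of Di nor its dose is given in the sources used here. Total RNA was made into biotin-labelled cRNA and hybridised to an Affymetrix human array by the standard protocol of the maker.

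The deposited values are log2 expression values that the authors made with GCRMA, a method that corrects background, normalises and summarises the probes of each probe set (version not given). No second normalisation was applied for the reported values. The range and the spread of the values were checked and fitted log2 values. An array gives no counting depth, so the number of arrays limits the precision. The array medians lay between 2.969 and 3.062 (log2), and 20617 to 21115 probe sets per array lay above a log2 value of 4. The lowest correlation between arrays of 1 group was 0.986 (Pearson, across probe sets, which are not independent replicates). No array duplicated another.

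Of 54675 probe sets, 62 control probe sets were left out. A gene table for the array paired 41097 probe sets with 1 gene symbol, 1801 with several and 11777 with none. Symbols were brought up to date with a table of current human gene names. A probe set was kept when it exceeded a log2 value of 4 in at least 3 of the 12 arrays, which kept 21715 probe sets, 18957 of them with 1 gene. Each gene was represented by its kept probe set with the highest mean. Probe sets whose name marks possible cross-hybridisation (suffix _x_at) were used only for genes with no other kept probe set, which applied to 355 genes. This left 10626 genes, of which 5011 had more than 1 kept probe set.

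A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated tests). The contrasts were Di minus control at 12 h, Di minus control at 48 h, the difference of these changes (48 h minus 12 h), and control at 48 h minus control at 12 h. P-values were adjusted by the Benjamini-Hochberg method over the 10626 genes, and a gene was called at an adjusted p under 0.05. Errors given beside log2 changes are standard errors of that fit, and errors beside group means are SDs of 3 arrays. A fold against a group whose mean lay under the log2 floor of 4 is given as a lower bound, the bright group's mean against the floor. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

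Before the data were examined, 25 gene lists with 438 genes were fixed, along with the tests, the alternatives and the rule for naming genes. Of the 438 genes, 331 were measured, meaning that a probe set passed the level filter, and none stood in more than 1 list. The 21 lists with at least 4 measured members were tested with limma's camera, which asks whether a list's genes moved against all other genes, at a preset inter-gene correlation of 0.01. The list p-values were adjusted over the 21 lists of a comparison. The same test with a correlation estimated from the residuals is given beside each call, and the rotation test fry was an alternative. Fry asks whether a list's genes moved, on balance, in 1 direction and does not compare them with other genes. Counts "adjusted over the list alone" use only the members of that list for the adjustment.

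The lists were NRF2 targets, p53 targets, ER chaperones and unfolded protein response, ATF4 and amino acid response, heat shock response, metallothioneins and zinc response, mitosis, DNA replication, homologous recombination and Fanconi repair, hypoxia and glycolysis, oxidative phosphorylation, sterol synthesis, NF-kB and cytokines, interferon response, immediate early genes, kidney injury markers, TGF-beta with matrix and epithelial-mesenchymal genes, AhR targets, ribosome biogenesis, autophagy and lysosome, and replication-dependent histones. Lists with fewer than 4 measured members were proximal tubule function, fibroblast markers, markers of other kidney segments, and endothelial and leukocyte markers. These are given gene by gene.

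The naming rule took, for each Di comparison, the 12 genes with the largest log2 change in each direction among called genes whose 3 Di values all lay beyond the 3 control values. For the other contrasts it took 5 in each direction. For each list called in a Di comparison it took the 4 members with the largest called change in the list's direction, filled up by the smallest p. HAVCR1, CDKN1A, HMOX1 and DDIT3 were named whatever their values. Other genes are named where a small count called for it, and were chosen after their values were seen.

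The alternatives were no filter, a floor of 6, eBayes with a trend and robust moderation, quantile normalisation on top, centring of each array on its median, the mean of all kept probe sets of a gene, every kept probe set on its own, a fit of only the groups compared, the replicate number as a block, each array left out in turn, an adjusted p under 0.01, and a log2 change of at least 1 as well. With no filter, a gene read by an _x_at probe set can be represented by a probe set that had failed the level filter. Such a probe set is dim and may miss a change, so its value cannot decide on the filtered one. The procedure was tested on simulated data in which 200 genes were changed by known amounts. Of genes changed by a log2 value of 1, the fit recovered 92.5% at 12 h, 94% at 48 h, 80.6% for the difference between times and 92.5% for time in control. At a log2 change of 0.5 these shares were 62.7%, 53.7%, 28.4% and 59.7%. False calls made up 3.55% to 5.75% of the calls. The simulated noise was drawn independently for each gene, and the other genes had 1 mean in all groups. In the real data far more genes were called, and genes need not vary independently. These shares therefore describe the fit and need not hold for the comparisons below.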

Results

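Gene expression was measured on 12 Affymetrix arrays of HK-2 cells treated with Di or with vehicle. Each of the 4 groups, Di and control at 12 h and at 48 h, held 3 arrays of biological replicates, and n = 3 per group applies to every value given. The deposited log2 values covered 54675 probe sets, from which 10626 genes were tested. Arrays of 1 group resembled one another closely, with correlations of 0.986 to 0.996 across probe sets. Between Di and control these were 0.980 to 0.991 at 12 h, which overlaps the range within groups, and 0.945 to 0.952 at 48 h. Replicate 2 of Di at 12 h lay farthest from its group mean, by a root mean square of 0.252 on the log2 scale against 0.111 to 0.182 for the other 11 arrays. The gap between the 3' and 5' probe sets of actin, a measure of RNA integrity and labelling, was 1.22 ± 0.239 (SD) in Di at 12 h and 1.71 ± 0.178 in control at 12 h (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays can give). At 48 h it was 1.40 ± 0.0773 in Di and 1.33 ± 0.127 in control (two-sided exact permutation p = 0.5). The same gap for GAPDH gave exact p-values of 0.3 at 12 h and 0.2 at 48 h.

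The comparison at 12 h asked which genes Di had changed early. Genes of the NRF2 programme, which serves glutathione synthesis and antioxidant defence, were the list with the smallest adjusted p, with 6 of 21 members higher. GCLM, a subunit of the enzyme that starts glutathione synthesis, rose by a log2 value of 0.89 ± 0.0806 (1.85-fold, adjusted p = 0.000343), and the thioredoxin reductase TXNRD1 rose by 0.87 ± 0.0684 (1.83-fold, adjusted p = 0.000223). HMOX1, the haem-degrading enzyme heme oxygenase 1, rose from 7.77 ± 0.0582 to 8.40 ± 0.0808 (SD), or 1.55-fold (adjusted p = 0.00137). HAVCR1, which encodes the tubular injury marker KIM-1, rose from 9.39 ± 0.289 to 10.54 ± 0.0559 (2.23-fold, adjusted p = 0.00132). TXNIP, an inhibitor of thioredoxin whose transcription follows glucose, fell from 9.62 ± 0.137 to 7.41 ± 0.197 (4.66-fold, adjusted p = 0.000223).

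Among the other genes with the largest increases at 12 h were the noncoding RNA LOC100190986 (log2 change 2.16 ± 0.235, adjusted p = 0.000706), AP1S1, a subunit of a clathrin adaptor (1.92 ± 0.389, adjusted p = 0.0103), and ZNF652, a zinc finger protein (1.59 ± 0.197, adjusted p = 0.00129). The increase of AP1S1 was larger than the spread of the 12 h groups (7.80 ± 0.372 in control, 9.72 ± 0.248 in Di). Its replicates in Di at 48 h spread widely, at 7.47, 9.48 and 8.53, so AP1S1 also varied between arrays of 1 group. EIF5A, a translation factor, rose by 1.23 ± 0.113 (adjusted p = 0.000343), and AP1S3, another adaptor subunit, by 1.12 ± 0.121 (adjusted p = 0.000706). FCF1, MIDN, BAX and MTPAP rose by log2 values of 1.25 to 1.38 (adjusted p between 0.00186 and 0.0145). FOLR1, a folate receptor, rose by 1.49 ± 0.209 (adjusted p = 0.00186), while its 1 other kept probe set was called in the opposite direction. None of the 3 other probe sets of MTPAP had the sign of the named one. Control at 12 h was the lower of the control groups for most of these genes. Without Di, ZNF652 lay at 6.80 to 7.31 at 12 h and at 8.96 to 9.36 at 48 h. FCF1 lay at 5.64 to 6.55 and at 7.23 to 7.28. The control arrays of LOC100190986, AP1S1, FOLR1, MIDN, BAX, MTPAP, EIF5A and HAVCR1 also lay higher at 48 h without overlap, and those of AP1S3 and FOSL1 lower. In Di at 48 h, replicate 1 was lowest and replicate 2 highest for all of these genes but FCF1 and FOSL1. A difference between arrays that moves these genes together was not tested. The 12 h changes are read against control at 12 h alone. The largest decreases after TXNIP were in the noncoding RNA LINC00537 (-1.48 ± 0.129, adjusted p = 0.000306) and in CCDC80, a matrix protein (-1.37 ± 0.219, adjusted p = 0.00409). ARRDC4, a relative of TXNIP, fell at least 1.45-fold (-1.18 ± 0.11, adjusted p = 0.000376), and CGN, which encodes the tight junction protein cingulin, fell by 1.12 ± 0.155 on the log2 scale (adjusted p = 0.00182). H2AC6, LINC00472, BLNK, DYNC2H1, PPIP5K1, DDIT4L and a probe set annotated to MIR146A, which does not measure the mature microRNA, completed the decreases, with log2 changes between -1.33 and -1.13 (adjusted p between 0.000645 and 0.0483). The Di means of LINC00537, H2AC6 and MIR146A lay under the floor, so their falls are bounded at 2.64-fold, 2.34-fold and 2.12-fold or more. With the mean of all probe sets the changes were 0.74 for ZNF652, 0.68 for EIF5A, 0.52 for FOLR1 and 0.24 for MTPAP, all still called. Without replicate 2 of Di at 12 h, H2AC6 stood at -0.85 and DDIT4L at -0.64, also still called.

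Of 21 gene lists tested at 12 h, 5 were called, 4 of them higher. NRF2 targets had 6 of 21 members higher and 0 lower (6 and 1 adjusted over the list alone, median log2 change 0.153, camera adjusted p = 1.27e-05, and adjusted p = 0.0125 with an estimated correlation). Besides GCLM, TXNRD1 and HMOX1 these were the cystine transporter SLC7A11 (0.79 ± 0.114), the sulfiredoxin SRXN1 (0.52 ± 0.0699) and the quinone reductase NQO1 (0.46). SLC7A11 stood at 0.52 with the mean of all probe sets. Immediate early genes, which answer growth factors and stress, had 4 of 13 members higher and 0 lower (6 and 1 adjusted over the list alone, median 0.197, adjusted p = 0.00165, and adjusted p = 0.0414 with an estimated correlation). FOSL1, an AP-1 transcription factor, led them at 1.17 ± 0.241 (adjusted p = 0.0109), followed by the mRNA decay factor ZFP36 (0.47 ± 0.116), the transcription factor EGR1 (0.46 ± 0.112) and the phosphatase DUSP1 (0.26 ± 0.0749, and 0.50 with the mean of all probe sets).

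ER chaperones and the unfolded protein response had 3 of 17 members higher and 0 lower (5 and 0 adjusted over the list alone, median 0.0943, adjusted p = 0.00953). They were the cochaperone DNAJC3 (0.83 ± 0.205), the secreted stress factor MANF (0.61 ± 0.0769) and SDF2L1 (0.49 ± 0.124). The lumenal chaperone CALR stood at 0.34 ± 0.102 (adjusted p = 0.0509). CALR was called with a floor of 6 (0.04), trend and robust moderation (0.0374), quantile normalisation (0.0212) and median centring (0.0119). It was also called without replicate 2 of Di at 12 h (0.0163) or replicate 1 of Di at 48 h (0.0396), and not in the other 14 alternatives. The list's call was lost with an estimated correlation (adjusted p = 0.0609), and 1 of 3 other probe sets of DNAJC3 was called in the opposite direction. The heat shock list had 1 of 13 members higher and 0 lower (1 and 0 adjusted over the list alone, median 0.0747, adjusted p = 0.0388), the cochaperone DNAJA1 (0.43 ± 0.0631, adjusted p = 0.00263). STIP1 (0.30), CHORDC1 (0.17) and HSP90AA1 (-0.10) did not pass, though STIP1 was called with the mean of all probe sets (0.69, adjusted p = 0.00784). The heat shock call was lost with an estimated correlation (adjusted p = 0.272), with quantile normalisation (0.0612), with fry (0.104), without replicate 1 of Di at 12 h (0.0517) and without replicate 1 of control at 12 h (0.105). TGF-beta, matrix and epithelial-mesenchymal genes were lower, with 0 of 16 members higher and 2 lower (0 and 4 adjusted over the list alone, median -0.194, adjusted p = 0.0326). The members that fell were the basement membrane collagens COL4A2 (-0.63 ± 0.0852, adjusted p = 0.00164) and COL4A1 (-0.56 ± 0.075, adjusted p = 0.00161), while TGFBI (-0.30) and ZEB1 (-0.19) did not pass. This call was lost with an estimated correlation (adjusted p = 0.272), with the mean of all probe sets (0.168, where ZEB1 stood at 0.002274) and without replicate 2 of control at 12 h (0.0584). TGFBI was called lower with the replicate number as a block (adjusted p = 0.0456) and without replicate 2 of Di at 12 h (0.0188). ZEB1 was called lower with no filter (adjusted p = 0.0259).

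The other 16 lists were not called at 12 h. Mitosis genes had 1 of 25 members higher and 6 lower (1 and 9 adjusted over the list alone, adjusted p = 0.0642), and DNA replication genes 0 of 25 higher and 4 lower (0 and 4 adjusted over the list alone, adjusted p = 0.0801). Mitosis was called lower with no filter (adjusted p = 0.00547), trend and robust moderation (0.0455), quantile normalisation (0.0247), only the 12 h arrays in the fit (0.0373) or fry (0.000746), and without replicate 2 of Di at 12 h (0.0162) or replicate 1 of Di at 48 h (0.0317). DNA replication was called lower with no filter (0.00584), only the 12 h arrays (0.0388) or fry (0.00903). Other lists were called in 1 alternative each, ATF4 targets with no filter (0.0448), sterol synthesis with the mean of all probe sets (0.0311) and kidney injury markers with fry (0.0446). The p53 targets had 5 of 19 higher and 2 lower (6 and 3 adjusted over the list alone, adjusted p = 0.0801). Their median was -0.0281 while their mean was 0.125 and the test pointed up. Members that rose included the cell cycle inhibitor CDKN1A (0.48 ± 0.0755, adjusted p = 0.00382), the stress cytokine GDF15 (0.59 ± 0.0747, adjusted p = 0.00132), GADD45A (0.49) and BAX. ATF4 targets had 5 of 20 higher and 2 lower (6 and 5 adjusted over the list alone, adjusted p = 0.105), with DDIT3, the stress transcription factor CHOP, at 0.56 ± 0.103 (adjusted p = 0.00712). Kidney injury markers had HAVCR1 and the growth factor HBEGF (0.65, adjusted p = 0.00862) higher of 13 (2 and 1 adjusted over the list alone, adjusted p = 0.113). Ribosome biogenesis had 3 of 15 higher (3 and 0 adjusted over the list alone, adjusted p = 0.129), interferon response 1 higher and 1 lower of 14 (2 and 1, adjusted p = 0.115), sterol synthesis 1 and 1 of 14 (1 and 1, adjusted p = 0.204), NF-kB and cytokines 2 and 2 of 14 (3 and 3, adjusted p = 0.516) and hypoxia and glycolysis 1 and 2 of 17 (1 and 2, adjusted p = 0.516). Autophagy and lysosome had 0 higher and 2 lower of 19 (0 and 2, adjusted p = 0.839) and histones 0 and 1 of 4 (0 and 1, adjusted p = 0.425). Metallothioneins (adjusted p = 0.677), homologous recombination (0.641), oxidative phosphorylation (0.5) and AhR targets (0.57) had 0 members past the threshold by either adjustment. The test pointed up against a negative median for oxidative phosphorylation (-0.0186), NF-kB (-0.0187), ribosome biogenesis (-0.0134) and autophagy (-0.0877). For metallothioneins (mean -0.00375) and hypoxia (mean -0.00755) it pointed up against a negative mean. The test reads a list against all other genes, and the median change of all tested genes at 12 h was -0.061.

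In all, 1453 of 10626 genes were called at 12 h, 414 higher and 1039 lower, and 37 of them changed at least 2-fold (16 higher, 21 lower). With each array centred on its median, 1353 genes were called and 735 of them (54.3%) were higher, against 28.5% without centring. The count was 745 without replicate 2 of control at 12 h and 778 without replicate 3, and 575 when only the 12 h arrays were fitted. In 3697 genes the 3 Di values did not overlap the 3 control values, where chance gives 10% of genes, or 1063. Of the other probe sets of genes called at 12 h, 71.1% had the same sign as the named one. The difference in the actin gap (-0.491) went with all 12 h results.

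Several of the named 12 h calls lay close enough to the threshold for 1 array to move them across it. BAX had an adjusted p of 0.06 without replicate 3 of control at 12 h. BLNK had 0.0515 and 0.0658 without replicates 1 and 2 of that group, and PPIP5K1 had 0.0813 and 0.0617 without its replicates 2 and 3 and 0.0519 without replicate 3 of Di at 12 h. For DNAJC3 the adjusted p was 0.06 and 0.0747 without replicates 1 and 3 of Di at 12 h and 0.0764 and 0.0545 without replicates 1 and 3 of control at 12 h. SDF2L1 had 0.0847 without replicate 3 of Di at 12 h and 0.0555 without replicate 2 of its control. ZFP36 had 0.0581 without replicate 2 of Di at 12 h and 0.0635 and 0.0892 without replicates 1 and 3 of its control. EGR1 had 0.056 and 0.0548 without replicates 2 and 3 of Di at 12 h. The call of MIR146A ended without any 1 of the 6 Di arrays (0.0525 to 0.112), without replicates 1 and 2 of control at 12 h (0.132 and 0.138) and without replicate 1 of control at 48 h (0.0614). The call of DDIT4L ended without any 1 of the Di arrays at 48 h (0.054 to 0.0636), the controls at 12 h (0.0822 to 0.128) or the controls at 48 h (0.0644 to 0.0675). Of the runs without 1 array, DUSP1 kept its call only in that without replicate 3 of control at 12 h (0.0528 to 0.152 without each of the other 11 arrays). Leaving out a 48 h array, which does not enter the 12 h contrast, left them at -1.33 for MIR146A, -1.18 for DDIT4L and 0.26 for DUSP1, and the p alone moved. Where a 12 h array was left out and the call ended, MIR146A lay between -1.49 and -1.14, DDIT4L between -1.30 and -1.09 and DUSP1 between 0.21 and 0.28. In those runs BAX stood at 1.13, BLNK at -1.07 and -1.04, PPIP5K1 between -1.15 and -1.03, DNAJC3 between 0.66 and 0.88, SDF2L1 at 0.42 and 0.32, ZFP36 between 0.36 and 0.45 and EGR1 at 0.39 and 0.46. With the replicate number as a block, MIR146A, DDIT4L and DUSP1 had adjusted p-values of 0.0786, 0.0718 and 0.0798. With only the 12 h arrays in the fit, H2AC6, DDIT4L, BLNK, PPIP5K1, DNAJC3, SDF2L1, ZFP36, EGR1 and DUSP1 had adjusted p-values of 0.0647 to 0.15. With the mean of all probe sets, FCF1 stood at 0.47 (adjusted p = 0.088), DYNC2H1 at -0.31 (0.0826) and EGR1 at 0.19 (0.325). With no filter, MIR146A, DDIT4L, PPIP5K1, DNAJC3 and SDF2L1 had adjusted p-values of 0.0525 to 0.118.

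**Figure D1:**
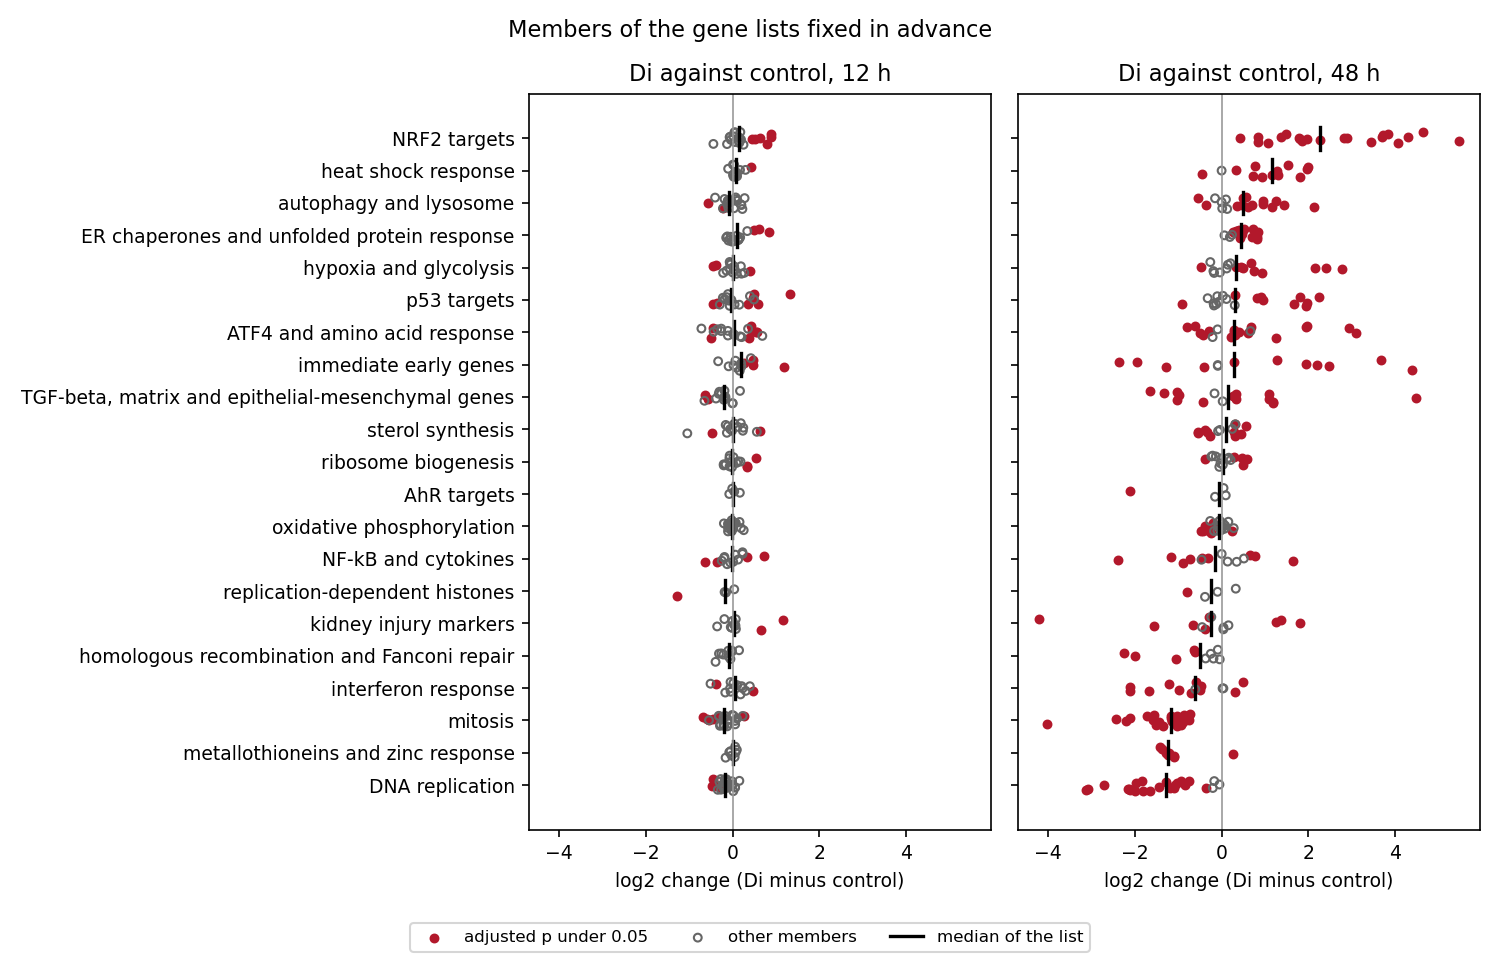
Log2 change (Di minus control, x axis) of each measured member of the 21 tested gene lists, at 12 h (left) and 48 h (right). Each circle is 1 gene, filled red at an adjusted p under 0.05 and open grey otherwise, and the black tick is the median of the list. At 48 h all 21 NRF2 targets lie to the right of 0 and all 25 mitosis genes to the left.

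The comparison at 48 h asked the same question after longer exposure. All 21 measured NRF2 targets rose. HMOX1 rose from 7.98 ± 0.0601 to 13.44 ± 0.134 (SD), or 44-fold (log2 change 5.46 ± 0.0807, adjusted p = 5.06e-12), SRXN1 rose 19.5-fold and GCLM 14.3-fold. All 25 measured mitosis genes fell, among them the kinesin KIF20A (at least 14-fold, adjusted p = 5.95e-09). The DNA helicase subunit MCM7 fell 8.7-fold (-3.12 ± 0.101) and RRM2, a subunit of the enzyme that makes deoxynucleotides, 8.4-fold (-3.07 ± 0.107). HAVCR1, higher at 12 h, fell from 9.87 ± 0.09 to 8.33 ± 0.234 (2.92-fold, adjusted p = 4.81e-06).

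Other genes with the largest increases at 48 h were MAP2, a microtubule-associated protein of neurons (29.9-fold, 4.90 ± 0.229, adjusted p = 2.08e-08), the cell surface proteoglycan GPC1 (16.4-fold, 4.03 ± 0.111) and the NRF2 target OSGIN1 (at least 7.97-fold, 4.07 ± 0.154). The Wnt inhibitor DKK1 rose at least 8.19-fold (4.50 ± 0.0639, adjusted p = 5.06e-12), and SNAI2, a repressor of epithelial genes, at least 7.97-fold (2.51 ± 0.0581 to 6.99 ± 0.18, adjusted p = 2.94e-11). The pseudogene NMRAL2P rose at least 9.47-fold, the AP-1 factor FOSL1 at least 9.62-fold and the adenosine receptor ADORA2B at least 7.05-fold. The log2 changes fitted for OSGIN1 and DKK1 rest partly on control values under the floor, and genes given as bounds are not ranked by size. The aldo-keto reductases AKR1C1 (24.9-fold, 4.64 ± 0.128) and AKR1C2 (19.8-fold, 4.31 ± 0.0868) were read by cross-hybridising probe sets of near-identical genes. With no filter, other probe sets, outside the filtered data, took their place and gave 0.02 for both (adjusted p = 0.57 and 0.615). CLDN2, the claudin that makes proximal tubule junctions permeable to cations, fell at least 23.3-fold (8.55 ± 0.0935 to 3.06 ± 0.0445, adjusted p = 3.89e-11). The methyltransferase TMT1A fell 32.9-fold (-5.04 ± 0.0768, adjusted p = 5.06e-12), SLC6A13, a transporter of GABA and taurine, 23.2-fold, and CYS1, which encodes the cilium protein cystin, 20.3-fold. The adhesion molecule VCAM1 fell 18.3-fold, the death ligand TNFSF10 17.8-fold, the metalloprotease ADAMTS9 17-fold and RASSF10 15.6-fold. BLNK fell at least 19.5-fold, FRMD4B at least 11.5-fold and the receptor kinase EPHA4 at least 10.2-fold. With the mean of all probe sets TMT1A stood at -2.64 and EPHA4 at -3.00. SLC6A13 was read by a cross-hybridising probe set. With no filter another probe set, which had failed the level filter, gave -0.64 (adjusted p = 0.00968).

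Of the 21 lists tested at 48 h, 12 were called, 7 higher and 5 lower. NRF2 targets had a median log2 change of 2.27 (21 higher and 0 lower, also adjusted over the list alone, adjusted p = 3.46e-19, and adjusted p = 0.000155 with an estimated correlation), from 0.43 for the ferritin subunit FTL to 5.46 for HMOX1. Heat shock genes had 11 of 13 members higher and 1 lower (11 and 1 adjusted over the list alone, median 1.16, adjusted p = 3.58e-06, and 0.0325 with an estimated correlation). DNAJB4 rose by 1.98 ± 0.157, HSPH1 by 1.97 ± 0.0801, BAG3 by 1.79 ± 0.118 and DNAJB1 by 1.53 ± 0.0932, and the small heat shock protein CRYAB fell by 0.46. ER chaperones had 14 of 17 higher and 0 lower (15 and 0 adjusted over the list alone, median 0.441, adjusted p = 2.3e-05, and 0.00838 with an estimated correlation). PDIA4 (0.84 ± 0.0801), DNAJB11 (0.82 ± 0.055), MANF (0.81 ± 0.0769) and HYOU1 (0.72 ± 0.0922) rose most. Autophagy and lysosome genes had 12 of 19 higher and 2 lower (12 and 2 adjusted over the list alone, median 0.499, adjusted p = 0.000282, and 0.0275 with an estimated correlation). The protease CTSL rose 4.4-fold (2.14 ± 0.0703), the autophagy receptor SQSTM1 2.69-fold (1.43 ± 0.0778), and the lysosomal enzyme GLA and the autophagosome protein GABARAPL1 by 1.25 ± 0.0862 and 1.16 ± 0.18.

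Hypoxia and glycolysis genes had 9 of 17 members higher and 1 lower (9 and 1 adjusted over the list alone, median 0.34, adjusted p = 0.00538, and 0.0325 with an estimated correlation). The peptide hormone ADM rose 6.84-fold, NDRG1 5.29-fold, the glucose transporter SLC2A1 4.42-fold and the hexokinase HK2 1.91-fold, while the lactate dehydrogenase LDHA fell by 0.47. HK2 stood at 0.42 with the mean of all probe sets, against 0.94. The p53 targets had 9 of 19 higher and 1 lower (9 and 1 adjusted over the list alone, median 0.302, adjusted p = 0.011). GDF15 rose 4.71-fold (2.24 ± 0.0747), the cell cycle inhibitor CDKN1A 3.5-fold (9.52 ± 0.0844 to 11.33 ± 0.0946), and PHLDA3 and AEN by 1.98 ± 0.0969 and 1.95 ± 0.168. GDF15 was read by a cross-hybridising probe set. With no filter another probe set, which had failed the level filter, gave 0.64 (adjusted p = 0.00129) and cannot decide on the larger rise. TP53I3 fell by 0.90, and BAX stood at 0.11 (adjusted p = 0.783). The p53 call was lost with an estimated correlation (adjusted p = 0.115). ATF4 targets had 12 of 20 higher and 5 lower (12 and 5 adjusted over the list alone, median 0.295, adjusted p = 0.0222). The transcription factor ATF3 rose 8.49-fold (3.09 ± 0.277), the secreted hormone STC2 7.61-fold (2.93 ± 0.17), and the amino acid transporter SLC7A5 and the phosphatase subunit PPP1R15A by 1.97 ± 0.165 and 1.94 ± 0.165. The lower members were the serine synthesis enzymes PHGDH and PSAT1, PCK2, VLDLR and DDIT4. This call was lost with an estimated correlation (adjusted p = 0.0613) and with quantile normalisation (0.0538). DDIT3 stood at 0.28 ± 0.103 (adjusted p = 0.0392).

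The 5 lists called lower at 48 h were mitosis, DNA replication, metallothioneins, homologous recombination and interferon response. Mitosis genes had a median of -1.16 (0 higher and 25 lower, also adjusted over the list alone, adjusted p = 1.72e-12, and 0.00113 with an estimated correlation). After KIF20A, the largest fitted falls were those of the kinetochore motor CENPE (at least 3.9-fold), the spindle protein NUSAP1 (-2.19 ± 0.0657) and the spindle kinesin KIF11 (-2.11 ± 0.127). The mean of CENPE with Di lay under the floor, so its place among them is not settled. DNA replication genes had 0 of 25 higher and 22 lower (0 and 22 adjusted over the list alone, median -1.29, adjusted p = 5.85e-12, and 0.00937 with an estimated correlation). After MCM7 and RRM2, the cyclin CCNE2 fell (-2.70 ± 0.17), and the replication licensing factor CDT1 fell at least 2.51-fold. Metallothionein genes, whose products bind zinc and copper, had 7 of 8 members lower and 1 higher (1 and 7 adjusted over the list alone, median -1.22, adjusted p = 0.000282, and 0.0325 with an estimated correlation). MT1F fell 2.66-fold (-1.41 ± 0.0783), followed by MT1X (-1.38 ± 0.106), MT1E (-1.27 ± 0.0663) and MT1G (-1.23 ± 0.101). The member that rose was the zinc exporter SLC30A1 (0.26). The named metallothioneins were read by cross-hybridising probe sets. With no filter another probe set, which had failed the level filter, gave 0.05 for MT1G (adjusted p = 0.748).

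Homologous recombination genes had 0 of 10 members higher and 5 lower (0 and 6 adjusted over the list alone, median -0.49, adjusted p = 0.017). The helicase BRIP1 fell at least 3.28-fold, and BARD1, the partner of BRCA1 (-1.99 ± 0.236), RAD51AP1 (-1.06 ± 0.193) and FANCI (-0.64 ± 0.113) fell as well. The list's call was lost with an estimated correlation (adjusted p = 0.141), and FANCI had an adjusted p of 0.0624 with the mean of all probe sets. Interferon response genes had 2 of 14 higher and 9 lower (2 and 9 adjusted over the list alone, median -0.602, adjusted p = 0.0218). IFI44L (-2.12 ± 0.18), IFI44 (-2.10 ± 0.177), IFITM1 (-1.66 ± 0.101) and IFIT1 (-1.21 ± 0.214) fell most, while IFIT2 (0.48) and IFIT3 (0.32) rose. The interferon call was lost with an estimated correlation (adjusted p = 0.342).

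The other 9 lists were not called at 48 h, though most held members that changed in both directions. Immediate early genes had 7 of 13 higher and 4 lower (adjusted p = 0.126), with the phosphatase DUSP5 (3.68), JUN (2.48) and KLF4 (2.19) higher besides FOSL1, and EGR1 (-2.36 ± 0.112), DUSP6 (-1.94) and JUNB (-1.29) lower. TGF-beta and matrix genes had 8 of 16 higher and 6 lower (adjusted p = 0.395). Besides SNAI2, the connective tissue factors CCN1 (1.19) and CCN2 (1.09) and the repressor ZEB1 (1.17) rose, while E-cadherin, CDH1 (-1.33), COL4A1 (-1.66) and COL4A2 (-1.02) fell. Kidney injury markers had 3 of 13 higher and 5 lower (adjusted p = 0.748). LCN2, which encodes NGAL (1.80), HBEGF (1.36) and CD44 (1.26) rose, and VCAM1, HAVCR1, CLU (-0.65), CST3 (-0.38) and TIMP1 (-0.29) fell. NF-kB and cytokine genes had 3 of 14 higher and 6 lower (adjusted p = 0.721), sterol synthesis 5 and 5 of 14 (0.748), oxidative phosphorylation 1 and 7 of 23 (0.395) and ribosome biogenesis 4 and 1 of 15 (0.395). AhR targets had 0 of 4 higher and 1 lower, CYP1B1 at -2.11 (0.539), and histones 0 of 4 higher and 1 lower, H2BC12 at -0.80 (0.447). For these 9 lists the counts adjusted over the list alone were the same. Oxidative phosphorylation was called with no filter (0.0315), and with fry 7 of the 9 were called (2.75e-09 to 0.0226), all but kidney injury markers and sterol synthesis.

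Of 10626 genes, 5413 were called at 48 h, 2436 higher and 2977 lower, and 1322 of them changed at least 2-fold (461 higher, 861 lower). In 6549 genes the Di and control values did not overlap, where chance gives 10%, or 1063. The call of DDIT3 ended without replicate 3 of Di at 12 h (0.0518), without replicates 1 and 3 of Di at 48 h (0.104 and 0.105), without replicates 1 and 2 of control at 12 h (0.0509 and 0.052) or of control at 48 h (0.155 and 0.0832), and with no filter (0.0664), quantile normalisation (0.157) or the replicate number as a block (0.059). Its change lay between 0.20 and 0.28 in these runs.

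**Figure D2:**
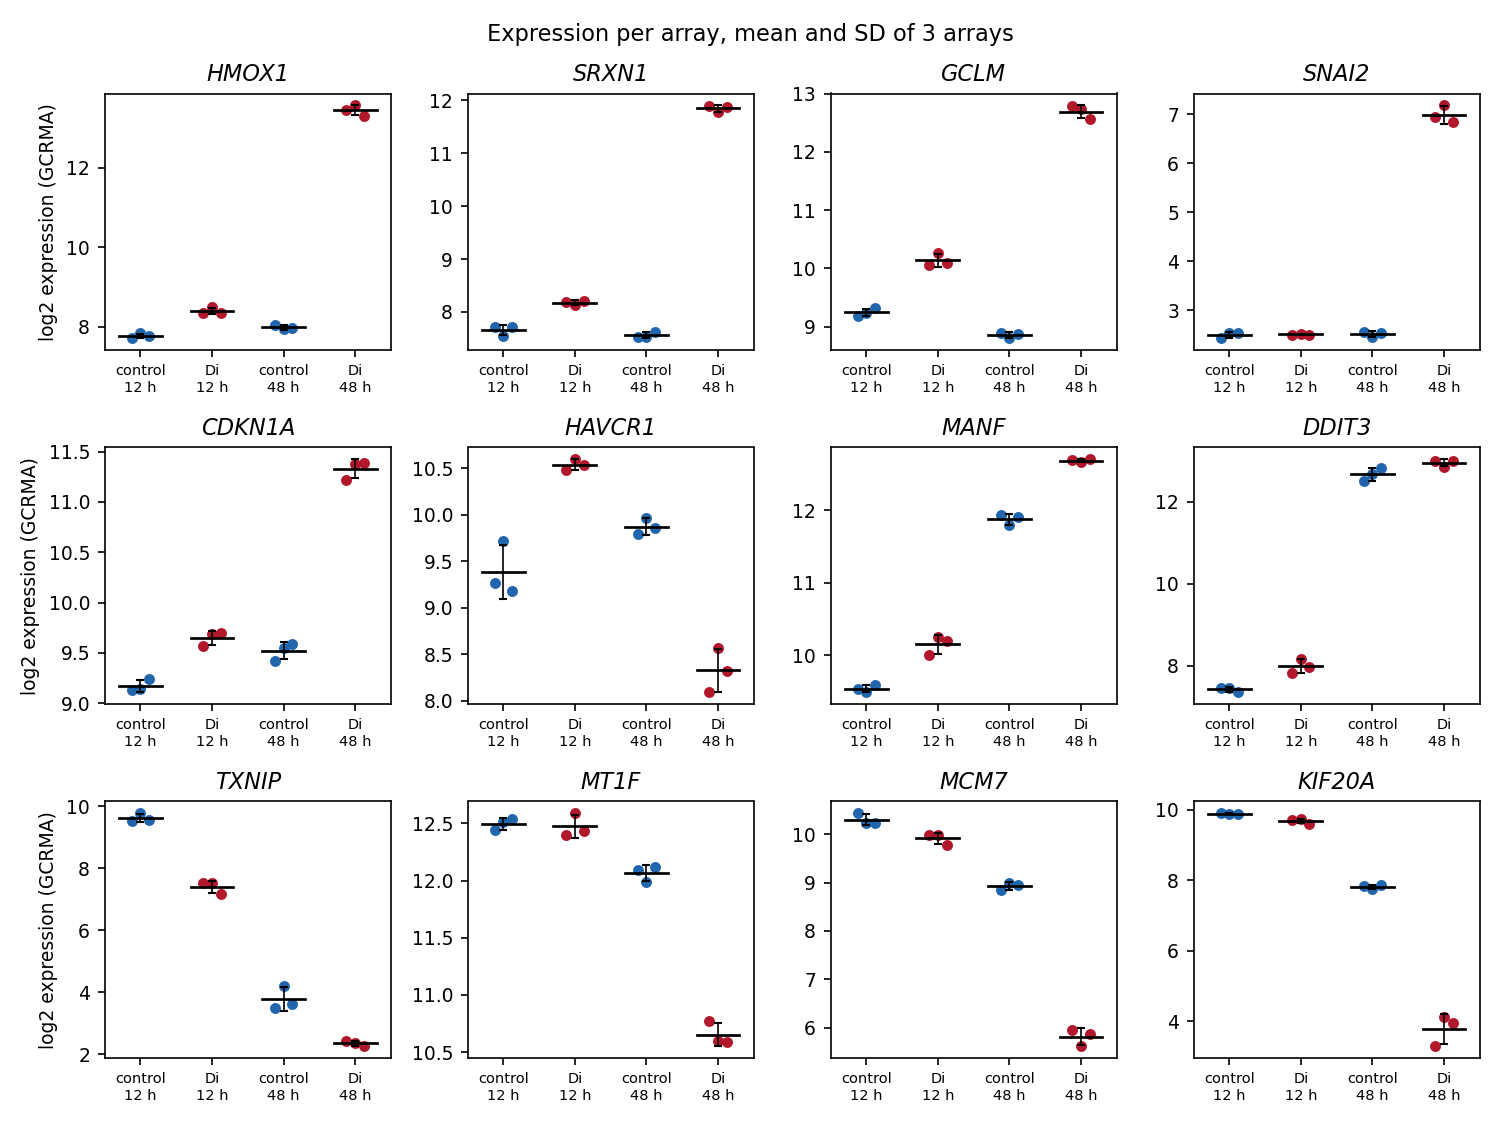
Log2 expression (y axis) of 12 named genes in each of the 12 arrays, by group (x axis), with control in blue and Di in red. The line is the mean and the bar the SD of 3 arrays. The mean of HMOX1 lies between 7.77 and 8.40 in 3 of the groups and at 13.44 in Di at 48 h, and HAVCR1 is higher with Di at 12 h and lower at 48 h.

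The interaction contrast asked which Di changes differed between 48 h and 12 h. The rise of HMOX1 was larger at 48 h by a log2 value of 4.83 ± 0.114 (adjusted p = 7.28e-10), and the change of HAVCR1 went from an increase to a decrease, a difference of -2.70 ± 0.205 (adjusted p = 2.89e-06). The naming rule also took the positive differences of MAP2 (5.29 ± 0.325) and AKR1C1 (4.71 ± 0.181) and the negative ones of TMT1A (-4.40 ± 0.109), TNFSF10 (-4.07 ± 0.155) and SLC6A13 (-4.00 ± 0.203). NMRAL2P (fitted difference 5.30) and DKK1 (4.49) lay under the floor in every group but Di at 48 h, and CLDN2 (-5.50) and EPHA4 (-4.11) in Di at 48 h. The fitted sizes of these 4 rest partly on background and do not rank them. With no filter the probe set that then represents AKR1C1 gave 0.03 (adjusted p = 0.53), and that of SLC6A13 gave -0.73 (adjusted p = 0.0376). Both had failed the level filter. With the mean of all probe sets TMT1A stood at -2.22 and EPHA4 at -2.34. CDKN1A had a difference of 1.33 ± 0.107 (adjusted p = 4.31e-06), and DDIT3 one of -0.28 ± 0.146 that did not pass (adjusted p = 0.162).

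Of 21 lists, 11 were called in this contrast, 6 higher and 5 lower. NRF2 targets differed in all 21 members (21 and 0 adjusted over the list alone, median difference 2.11, adjusted p = 2.02e-19, and 0.000148 with an estimated correlation). Mitosis genes had 23 of 25 members lower (0 and 25 adjusted over the list alone, median -1.03, adjusted p = 8.19e-13, and 0.00108 with an estimated correlation). DNA replication genes had 1 higher and 22 lower of 25 (1 and 23 adjusted over the list alone, median -1.31, adjusted p = 8.19e-13, and 0.00999 with an estimated correlation), led by RRM2 (-2.88), MCM7 (-2.73), CCNE2 (-2.63) and GINS2 (-2.09). Metallothioneins had 1 higher and 7 lower of 8 (1 and 7 adjusted over the list alone, median -1.23, adjusted p = 3.68e-05, and 0.0265 with an estimated correlation). Autophagy and lysosome genes had 11 higher and 1 lower of 19 (12 and 1 adjusted over the list alone, median 0.659, adjusted p = 0.000281, and 0.0265 with an estimated correlation), among them the protease CTSD (-0.56 at 12 h, 0.61 at 48 h) and the autophagy kinase ULK1 (difference 1.18). ER chaperones had 7 of 17 higher and 0 lower (7 and 1 adjusted over the list alone, median 0.292, adjusted p = 0.00742, and 0.0431 with an estimated correlation), with HSP90B1 at 0.75 ± 0.156.

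The remaining 5 calls were lost with an estimated correlation. Heat shock genes had 11 of 13 higher and 1 lower (11 and 1 adjusted over the list alone, median 0.845, adjusted p = 3.5e-05, and adjusted p = 0.0514 with an estimated correlation), led by HSPH1 (1.95) and DNAJB4 (1.89). Interferon genes had 1 of 14 higher and 8 lower (1 and 9 adjusted over the list alone, median -0.648, adjusted p = 0.00193, and 0.183 with an estimated correlation), led by IFI44 (-2.20). The p53 targets had 10 of 19 higher and 3 lower (10 and 3 adjusted over the list alone, median 0.485, adjusted p = 0.0119, and 0.131 with an estimated correlation), led by GDF15 (1.64, and 0.60 with no filter, where a probe set that failed the filter represents it). Hypoxia and glycolysis genes had 7 of 17 higher and 2 lower (8 and 2 adjusted over the list alone, median 0.333, adjusted p = 0.0145, and 0.0514 with an estimated correlation), led by NDRG1 (2.86), and homologous recombination 0 of 10 higher and 4 lower (0 and 4 adjusted over the list alone, median -0.31, adjusted p = 0.022, and 0.163 with an estimated correlation). The homologous recombination call was also lost with the mean of all probe sets (0.0985), as was that of BRCA1 (-0.59, then -0.20, adjusted p = 0.147). With that mean BRIP1 stood at -1.07 against a fitted -1.92, and HK2 at 0.38 against 0.97. MT1G stood at -0.06 with no filter (adjusted p = 0.766), where a probe set that failed the filter represents it. RAD51AP1 (-0.85, adjusted p = 0.0299) was not called without replicates 1 or 3 of Di at 12 h (0.0651 and 0.0672), replicate 1 of Di at 48 h (0.0671), replicate 3 of control at 12 h (0.0722) or replicates 1 or 2 of control at 48 h (0.0588 and 0.0693), nor with no filter (0.0774) or the replicate number as a block (0.0543), while its difference lay between -0.85 and -0.69. Lists not called in this contrast were ATF4 targets (adjusted p = 0.12), TGF-beta and matrix genes (0.175), oxidative phosphorylation (0.277), immediate early genes (0.34), kidney injury markers (0.413), AhR targets (0.413), NF-kB (0.453), histones (0.653), sterol synthesis (0.867) and ribosome biogenesis (0.867). Of these, ATF4 targets were called with the mean of all probe sets (0.0303) and oxidative phosphorylation with no filter (0.0201). Fry called both, along with immediate early genes, kidney injury markers, TGF-beta and matrix genes and AhR targets (5.32e-07 to 0.0469). The test pointed down against a positive median and mean for sterol synthesis (0.00292 and 0.0198), and histones had a median of -0.164 and a mean of 0.158. In all, 4067 genes were called, 2100 higher and 1967 lower, 1199 of them by at least 2-fold.

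The overlap of the 12 h and 48 h changes asked whether the early changes were also present later. Of 909 genes called at both times, 684 (75.25%) had the same direction. The 212 higher at both times, against 94.9 for independent calls, included HMOX1, GCLM, SRXN1, TXNRD1, GDF15, CDKN1A, FOSL1 and MANF. The 472 lower at both times, against 291 for independent calls, included CGN, BLNK, COL4A1 and COL4A2. HAVCR1 and FOLR1 were among 50 genes higher at 12 h and lower at 48 h (116 for independent calls), and CTSD among 175 that went the other way (238). Of the 37 genes changed at least 2-fold at 12 h, 15 were called in the same direction at 48 h, 6 in the opposite one and 16 not at all. The log2 changes at both times correlated across genes with Pearson r = 0.259 and Spearman rho = 0.249, where genes are not independent replicates. The comparisons used separate control arrays but shared the estimate of each gene's spread. Genes with a small spread are called more readily at both times, so the numbers for independent calls are a reference only. The count of 684 was 344 without replicate 2 of control at 12 h, 378 without replicate 3 of that group, 453 without replicate 3 of Di at 12 h, and 299 when only the groups compared were fitted.

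**Figure D3:**
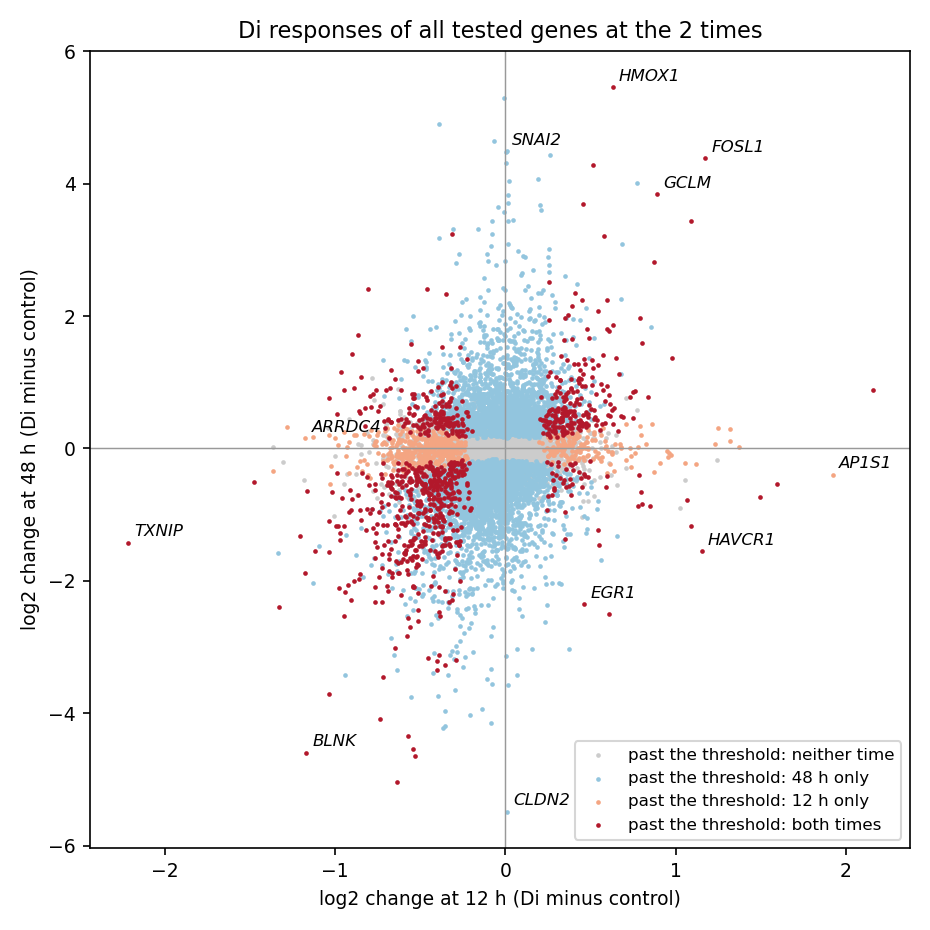
Log2 change (Di minus control) of all 10626 tested genes at 12 h (x axis) and at 48 h (y axis), coloured by the times at which the gene passed the threshold. HMOX1 lies at 0.63 and 5.46, HAVCR1 lies at 1.15 and -1.55, and CLDN2 is near 0 at 12 h and at -5.49 at 48 h.

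The control arrays alone asked what changed in culture between 12 h and 48 h without Di. Genes of the stress response to amino acid shortage and misfolded protein rose. DDIT3 rose from 7.43 ± 0.063 to 12.68 ± 0.158 (SD), or 38.1-fold (adjusted p = 1.53e-10), ATF3 36.3-fold, and INHBE, an activin subunit, 39.2-fold (7.11 ± 0.0689 to 12.41 ± 0.0359). The stress factor NUPR1 rose at least 23.5-fold and BEX2 19.8-fold. TXNIP fell from 9.62 ± 0.137 to 3.77 ± 0.387, or at least 49.3-fold (adjusted p = 1.25e-09). The collagenase MMP1 fell at least 10.6-fold, the replication factor MCM10 at least 10.4-fold, the sodium channel SCN3A at least 6.58-fold and the hyaluronan-binding protein TNFAIP6 at least 4.06-fold.

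Of 21 lists, 10 were called in control over time, 3 higher and 7 lower. All 17 ER chaperone genes rose (17 and 0 adjusted over the list alone, median 1.97, adjusted p = 1.28e-16, and 0.000222 with an estimated correlation), and 18 of 20 ATF4 targets rose with 0 lower (18 and 0 adjusted over the list alone, median 1.75, adjusted p = 4.04e-15, and 0.000222 with an estimated correlation). All 25 mitosis genes fell (0 and 25 adjusted over the list alone, median -1.94, adjusted p = 1.88e-15, and 0.000344 with an estimated correlation), as did 24 of 25 DNA replication genes (0 and 24 adjusted over the list alone, median -1.58, adjusted p = 5.66e-14, and 0.00583 with an estimated correlation). Homologous recombination genes were lower in 9 of 10 (0 and 9 adjusted over the list alone, median -1.75, adjusted p = 2.85e-05, and 0.0341 with an estimated correlation). The other 5 calls were lost with an estimated correlation. These were autophagy and lysosome (10 higher and 4 lower of 19, median 0.354, adjusted p = 0.0106, and 0.103 with an estimated correlation), oxidative phosphorylation (1 and 12 of 23, median -0.272, 0.00803 and 0.271), heat shock (0 and 9 of 13, median -0.484, 0.00932 and 0.242), metallothioneins (1 and 7 of 8, median -0.633, 0.0106 and 0.137) and TGF-beta and matrix genes (1 and 10 of 16, median -0.273, 0.0114 and 0.271). Adjusted over the list alone, their counts were the same except for 13 lower in oxidative phosphorylation.

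The 11 lists not called in control over time were p53 targets (7 higher and 4 lower of 19, adjusted p = 0.166), interferon response (6 and 3 of 14, 0.188), histones (2 and 1 of 4, 0.188), ribosome biogenesis (1 and 7 of 15, 0.381), immediate early genes (2 and 5 of 13, 0.403), NRF2 targets (5 and 9 of 21, 0.608), sterol synthesis (3 and 6 of 14, 0.617), NF-kB and cytokines (3 and 2 of 14, 0.617), kidney injury markers (3 and 6 of 13, 0.617), AhR targets (2 and 1 of 4, 0.697) and hypoxia and glycolysis (4 and 7 of 17, 0.942). The test pointed up against a negative mean for AhR targets (-0.253) and NF-kB (-0.00501). In all, 5621 genes were called, 2323 higher (41.3%) and 3298 lower, 1159 of them by at least 2-fold. With each array centred on its median, 51.5% of 5596 called genes were higher. The 3' minus 5' gap differed between the control groups by -0.384 for actin and -0.126 for GAPDH (48 h minus 12 h, two-sided exact permutation p = 0.1 for each, the smallest that 3 against 3 arrays can give), and this went with all changes over time. The groups at each time were 1 set of control arrays, and no array or culture batch is given in the labels.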

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

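Of the tests in this part, that of replicate 2 of Di at 12 h as the only source was chosen after the result was seen, while the run without that array had been planned. The results listed are of 2 kinds. For the first, the change with Di differed between 12 h and 48 h by the test of the difference itself. The second is signal in probe sets that the report's comparisons do not use.

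The Di change differed between the times for 4067 genes and for 11 gene lists. With an estimated correlation 5 of the 11, heat shock (adjusted p = 0.0514), hypoxia and glycolysis (0.0514), p53 targets (0.131), homologous recombination (0.163) and interferon response (0.183), lost the call, which left 6. The median differences (48 h minus 12 h, log2) of the lists that differed upward were 2.11 for NRF2 targets, 0.845 for heat shock, 0.659 for autophagy and lysosome, 0.485 for p53 targets, 0.333 for hypoxia and glycolysis and 0.292 for ER chaperones. The median differences of those that differed downward were -1.31 for DNA replication, -1.23 for metallothioneins, -1.03 for mitosis, -0.648 for interferon response and -0.31 for homologous recombination. Of 100 drawn splits within each time, 1, the real one, reached 4067 genes (highest other 3652). The 7 draws that kept the real 48 h split gave at least 3174 genes. The rest gave at most 1, an outcome fixed by breaking the 48 h groups, and 7 draws are too few for a share under 0.05. For the lists, 7 of 100 splits gave at least 11 (highest other 13). All 7 kept the real 48 h split and with it the real Di change at 48 h. The highest number among the rest was 9. These draws cannot tell whether chance would give 11 lists.

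Antioxidant and detoxifying genes with a larger rise at 48 h were HMOX1 (4.83), AKR1C1 (4.71), AKR1C2 (4.31), OSGIN1 (3.87), SRXN1 (3.77), GCLM (2.95), TXNRD1 (1.94) and SLC7A11 (1.18). Others among the most changed genes with a higher value at 48 h were NMRAL2P (5.30), MAP2 (5.29), DKK1 (4.49), SNAI2 (4.48), ADORA2B (4.17), GPC1 (4.01) and FOSL1 (3.21). Stress genes followed with STC2 (3.04), ATF3 (2.40), PPP1R15A (1.77), GDF15 (1.64), PHLDA3 (1.62), SLC7A5 (1.61), AEN (1.55) and CDKN1A (1.33). Chaperones were HSPH1 (1.95), DNAJB4 (1.89), BAG3 (1.78), DNAJB1 (1.52), CHORDC1 (1.12), PDIA4 (0.99), STIP1 (0.86), DNAJA1 (0.84), HSP90AA1 (0.82), HYOU1 (0.81), HSP90B1 (0.75) and DNAJB11 (0.65). Lysosome and autophagy genes were CTSL (2.10), SQSTM1 (1.24), CTSD (1.18), ULK1 (1.18), GLA (1.02) and GABARAPL1 (0.89). Glycolysis and hypoxia genes were NDRG1 (2.86), ADM (2.83), SLC2A1 (1.75) and HK2 (0.97). Immediate early and matrix genes were DUSP1 (1.68), ZEB1 (1.36), ZFP36 (0.81) and TGFBI (0.62), and BEX2 had 0.52. Positive differences of genes that were lower at 12 h were those of H2AC6 (1.61), PPIP5K1 (1.3), CCDC80 (1.02) and DYNC2H1 (0.53). The differences of ARRDC4 (1.33), LINC00537 (0.98) and TXNIP (0.80) are not readable as a smaller response at 48 h, because Di at 48 h lay under the floor, along with control at 48 h, and for ARRDC4 and LINC00537 also Di at 12 h. The fitted differences of NMRAL2P, DKK1, SNAI2, ADORA2B, OSGIN1 and FOSL1 also rest partly on values under the floor, at least in control at 48 h, as do those of H2AC6 and STC2 in Di at 12 h and CCDC80 in Di at 48 h.

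Negative differences of the most changed genes were those of CLDN2 (-5.50), TMT1A (-4.40), EPHA4 (-4.11), TNFSF10 (-4.07), SLC6A13 (-4.00), FRMD4B (-3.85), VCAM1 (-3.84), CYS1 (-3.77), RASSF10 (-3.61), BLNK (-3.42) and ADAMTS9 (-3.35). Those of CLDN2, EPHA4, FRMD4B, BLNK, KIF20A, CENPE, CDT1 and BRIP1 rest partly on values under the floor in Di at 48 h. Cell cycle and repair genes were KIF20A (-3.82), RRM2 (-2.88), MCM7 (-2.73), CCNE2 (-2.63), GINS2 (-2.09), BRIP1 (-1.92), BARD1 (-1.90), KIF11 (-1.90), CENPE (-1.90), NUSAP1 (-1.88), CDT1 (-1.81), RAD51AP1 (-0.85) and BRCA1 (-0.59). Interferon genes were IFI44 (-2.20), IFITM1 (-1.89), IFI44L (-1.61) and IFIT1 (-1.22), and metallothioneins were MT1X (-1.48), MT1F (-1.39), MT1E (-1.32) and MT1G (-1.29). EGR1 had -2.82, COL4A1 -1.09 and COL4A2 -0.39. Genes higher with Di at 12 h and with a negative difference were HAVCR1 (-2.70), AP1S1 (-2.32), FOLR1 (-2.22), ZNF652 (-2.13), FCF1 (-1.35), AP1S3 (-1.35), LOC100190986 (-1.27), BAX (-1.21), EIF5A (-1.16), MIDN (-1.03) and MTPAP (-0.94). For all of these but AP1S3, the control arrays at 48 h also lay above those at 12 h. The replicates of AP1S1 in Di at 48 h ran from 7.47 to 9.48.

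Among 2758 kept probe sets without a single gene, 274 were called at 12 h (125 higher, 149 lower) and 1080 at 48 h (457 higher, 623 lower), each against the control arrays of its time. They were not assigned to genes.

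The 37 genes that changed at least 2-fold at 12 h were weighed against 3 technical explanations. A difference in RNA quality stays open. The shift predicted from the actin gap was 0.265 (95% interval 0.0693 to 0.461) and the observed one 1.26. The interval lay wholly in the observed direction. The 37 genes had been chosen in the same arrays for a change of at least 2-fold. That choice alone set a large observed shift, so the comparison cannot decide. Replicate 2 of Di at 12 h as the only source was argued against, since 35 of the 37 were called without it. Signal of single probe sets stays open, because 67.6% of 34 other probe sets of these genes had the same sign (95% interval 49.5 to 82.6) against 96% for 2-fold genes at 48 h. An effect of Di stays open beside these.

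The fall of 7 metallothionein genes at 48 h may be the fall of fewer transcripts, read by several cross-hybridising probe sets. Their log2 changes lay between -1.41 and -1.10 and their SD was 1.5 times the median standard error (0.123 against 0.082), which is what shared signal would give. Genes that truly fall together would give similar values as well. Which members fell therefore stays open, as does an effect of Di on each of them.

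For the counts that compare 3 with 3 arrays, the 10 splits are too few for a share under 0.05. The real split gave 1453 genes at 12 h (highest other 1), 5413 at 48 h (highest other 1) and 5621 in control over time (highest other 0). It gave 5 lists at 12 h (highest other 2), 12 at 48 h (highest other 9, lowest 5) and 10 in control over time (highest other 9, lowest 6). In each of these the real split was the 1 of 10 with as large a count. Splits that mixed the groups called several lists at the preset correlation at 48 h and in control over time, and 0 to 2 at 12 h. Each of them still set 2 arrays of 1 group with 1 of the other, and so kept part of the real difference. Their counts therefore measure neither chance nor a rate of false list calls. For the 684 genes changed the same way at both times, 1 of 100 drawn splits, the real one, reached the count (highest other 0). That outcome was fixed by the splits at single times, which called at most 1 gene, so it says nothing on whether the shared direction exceeds chance.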

How the results depend on the processing

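All alternatives were chosen in advance. For the named genes, counting each gene with each alternative other than leaving out an array, 308 results kept direction and call at 12 h, 545 at 48 h, 359 in the difference between times and 80 in control. Calls were lost in 20, 6, 5 and 0 and gained in 7 at 12 h. With 1 array left out, 467, 821, 618 and 120 kept both, 46, 7, 6 and 0 lost the call, and 3 at 12 h gained one. For the gene lists, 191 results kept both at 12 h, 195 at 48 h and 173 in the difference, with 6, 5 and 6 lost and 11, 8 and 8 gained. With 1 array left out these were 247, 252 and 252, and 3 were lost and 2 gained, all at 12 h. ZEB1 turned from -0.19 to 0.002274 at 12 h with the mean of all probe sets. MT1G stood at 0.04954 against -1.23 at 48 h with no filter, where a probe set that failed the filter represents it.

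The number of called genes changed by over 1.5 times as follows. With every probe set on its own, which tests more features, it was 2579 at 12 h, 9983 at 48 h, 7308 for the difference between times and 10363 in control, and the overlap was 1093. A log2 change of at least 1 gave 37, 1322, 1199 and 1159, and an adjusted p under 0.01 gave 442 at 12 h and 2671 for the difference, by stricter thresholds. A fit of only the groups compared, with fewer arrays to estimate the spread, gave 575 at 12 h and an overlap of 299. This fit has no form for the difference between times and was not run there. Called lists were 8 at 12 h with no filter, where the cause was not tested. An estimated correlation gave 2 lists at 12 h and 6 for the difference, and fry, which does not compare a list with other genes, 19 at 48 h and 17 for the difference. With 1 array left out, the counts ranged from 745 to 1457 at 12 h, 4735 to 5900 at 48 h, 3555 to 4418 for the difference and 4848 to 6155 in control, the overlap from 344 to 653, and the lists from 4 to 6, 12 to 12 and 11 to 11. The lowest counts at 12 h were those without replicate 2 (745) and replicate 3 (778) of control at 12 h. Without replicate 2 of Di at 12 h, 1323 genes were called there, 1039 of them shared with the 1453. The labels do not say whether the replicate numbers pair the arrays. Of 18 pairs of the same number, 3 correlated above 0.1, which does not settle it. With the numbers as a block the counts were 1003, 5076, 3645 and 5257. Signals under the log2 floor of 4 limit what can be said of dim genes, since folds there are bounds.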

Other observations

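The gene families in this part, their tests, the array batch test and the RNA quality test were chosen after the data were seen. The glucose test was prompted by the fall of TXNIP. In the Di comparisons, 19 families were tested with camera, and 4 were called at 12 h. Collagens had 8 of 18 members lower and 0 higher (median log2 change -0.558, adjusted p = 3.44e-05, and 0.0605 with an estimated correlation), including COL4A3 (-1.04) and COL4A4 (-0.72) of the basement membrane. Laminins had 5 of 8 lower (median -0.582, adjusted p = 0.00261, and 0.162 with an estimated correlation), with LAMA5 at -0.73 and LAMB1 at -0.59. Proteasome subunits had 5 of 33 higher (median 0.19, adjusted p = 6.9e-07, and 0.193 with an estimated correlation), and mitochondrial ribosomal proteins 9 of 75 (median 0.118, adjusted p = 9.33e-08, and 0.222 with an estimated correlation). At 48 h, proteasome subunits had 20 of 33 higher and 1 lower (median 0.286, adjusted p = 0.000251, and 0.382 with an estimated correlation). Cytoplasmic tRNA synthetases had 12 of 14 higher (median 0.389, adjusted p = 0.000251, and 0.15 with an estimated correlation), with GARS1 at 0.77, CARS1 at 0.71 and WARS1 at 0.63. Aldo-keto reductases had 4 of 6 higher and 1 lower (median 3.65, adjusted p = 0.0166, and 0.15 with an estimated correlation), with AKR1B10 at 3.70 and AKR1C3 at 3.59. The other members that rose, AKR1C1 and AKR1C2, were read by cross-hybridising probe sets of near-identical genes. They stood at 0.02 each with no filter, where probe sets that failed the filter represent them. The count and median rest partly on them, here and in the difference between times. TRiC chaperonin subunits had 4 of 7 higher (median 0.248, adjusted p = 0.0346, and 0.15 with an estimated correlation). The families called at 48 h also changed in control over time, though none with an estimated correlation. Lower there were proteasome subunits (24 of 33, 1 higher, median -0.363, adjusted p = 0.000392), TRiC subunits (6 of 7, median -0.371, 0.0225) and aldo-keto reductases (4 of 6, median -0.777, 0.0225). The tRNA synthetases had 10 of 14 higher and 3 lower (median 0.862, adjusted p = 0.000308). In the difference between times, the aldo-keto reductases (median 3.53, adjusted p = 0.012, and 0.159 with an estimated correlation) and tRNA synthetases (median 0.419, adjusted p = 0.00266, and 0.159 with an estimated correlation) were called. The symbol patterns that define some families were narrowed after a first run had taken in antisense RNAs and interacting proteins, and the calls were not changed by that.

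Genes of the lists with too few measured members for a test also moved. Of the proximal tubule genes, the amino acid transporter subunit SLC3A1 fell at 12 h (-0.58, adjusted p = 0.0072) and at 48 h (-2.83, adjusted p = 3.82e-09), and the drug exporter ABCB1 fell at both times (-0.41, adjusted p = 0.00459, and -1.18, adjusted p = 1.01e-07). The peptidase DPP4 fell at 48 h (-0.39, adjusted p = 0.00766) and stood at 0.09 at 12 h (adjusted p = 0.602). Of the other 18 genes of that list, 16 were named in the gene table but had no probe set that passed the level filter, and 2 were not named there. Of the fibroblast markers, DCN stood at 0.00 at 12 h (adjusted p = 0.981) and fell at 48 h (-1.01, adjusted p = 2.12e-06), and LUM stood at -0.25 (adjusted p = 0.508) and fell by 0.72 (adjusted p = 0.0217). DCN was bright in all groups, with group means between 8.89 and 11.05. Of the markers of other kidney segments, the water channel AQP3 stood at 0.08 at 12 h and fell at 48 h (-1.71, adjusted p = 0.000737), AQP2 stood at 0.13 and -0.00 without passing, and of 10 endothelial and leukocyte markers, 9 were named in the gene table and 0 passed the level filter.

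The rise of ER chaperone and ATF4 genes in control between 12 h and 48 h had a median log2 change of 1.94 over both lists (mean 2.15). The actin gap within groups did not predict this rise, with a predicted shift of -0.0425 (95% interval -0.0921 to 0.00706). That does not decide on a difference in RNA quality between the control groups. Their gaps did not overlap (1.55 to 1.90 at 12 h, 1.19 to 1.43 at 48 h), while the slope came from the scatter within groups. The 2 lists were also picked after their shift was seen. A difference in RNA quality stays open. The medians of 18 of the 19 other tested lists lay below 1.94 by more than the SD of their members. They ran from -1.94 for mitosis to 0.354 for autophagy and lysosome. The exception was the histone list (median 0.377, SD 1.59, 4 genes). These values cannot decide on a batch of arrays shifting all lists alike. The deposited values had been normalised, which would have removed such a shift (median change of all genes -0.061). A looser form of the test, tried first, compared only the highest of these medians (0.377) with 0.5 times 1.94. It would have excluded such a batch, which it could not decide either. No label gives a batch, and a batch acting on some genes only was not tested. A shortage of glucose in the medium by 48 h may have contributed, as a hypothesis. It predicted a fall of ARRDC4, which like TXNIP is transcribed in response to glucose, and ARRDC4 fell at least 1.45-fold (fitted change -1.49, with control at 48 h under the floor). That leaves the hypothesis open, because TXNIP prompted it, the ER chaperone HSPA5 belongs to the pattern itself, and glucose was not measured.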
